A study of Brassica napus with 6 samples.

How the data were processed

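Poly(A) RNA was sequenced from cotyledons of oilseed rape (Brassica napus, an allotetraploid whose genome joins an A and a C subgenome) in 6 libraries, 3 of the wild type (WT) and 3 of a bnsdp1 mutant. Per the labels' protocols, seedlings grew on medium with 1% sucrose for 4 days in the dark and were then kept for 6 h under normal conditions, and mRNA was enriched on oligo(dT) beads. The labels do not state whether the replicates came from separate sets of seedlings, so p-values measure only the spread between these libraries, which may be technical. Each library's genotype and replicate number were taken from its labels.

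The deposited values are raw counts of reads per gene, per the file headers, which have the columns that featureCounts writes. The authors named fastp, HISAT2 and featureCounts in the submitters' processing notes; their versions and settings are not given in the sources used here. The genome build, the use of strand and the treatment of reads that match several places are likewise not given in the sources used here. Each file held 100919 genes on 884 sequences, which included 10 A chromosomes and 9 C chromosomes, with 3998 genes on unplaced sequences. In 100% of rows the stated gene length equalled the full distance from gene start to gene end, so the deposited counts were made over whole gene spans and can include reads from introns. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart. Reads shared by near-identical copies, such as the A and C copies of a gene, may be split between them or left out, so the value of a single copy is uncertain where its partner is close in sequence.

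Total counts were between 48288744 and 65550668 per library. At this depth the counting error is small for all but the lowest genes, and the spread between replicates limits the tests. Ratios over small counts are given with an exact (Clopper-Pearson) 95% binomial interval on summed reads, which covers counting error only, as the labels name no molecular identifiers.

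Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the genotypes as groups, libraries were scaled by TMM, and the quasi-likelihood F test (glmQLFit and glmQLFTest, robust set to FALSE) compared mutant with WT with no covariate. A gene was called changed at a Benjamini-Hochberg false discovery rate (FDR) under 0.05, and 2-fold changes additionally needed an absolute log2 fold change of at least 1. Levels are CPM (counts scaled to a common library size in the usual way) after TMM scaling. The fit was tested on simulated counts of 56385 genes, drawn from the observed means and dispersions, of which 200 were changed. It recovered 2% of genes changed 1.25-fold, 16.3% at 1.5-fold, 64% at 2-fold and 87.2% at 4-fold, with 13 false calls. With so few changed genes the FDR threshold is stricter than in the real comparison, so these shares do not give the recovery there.

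Named genes followed a rule that was fixed before the data were examined, which limits the text to 2 identifiers that rose and 2 that fell where no table pairs identifiers with names. The files do not pair their identifiers with gene names. A table of 123214 named genes from another assembly (Da-Ae) was searched and matched 0 identifiers. Chosen genes had an FDR under 0.05, a mean of at least 5 CPM over the 6 libraries, mutant values all on the same side of the WT values, and the largest fitted changes. For the same reason the planned comparisons of the SDP1 copies and of 32 gene lists, which cover storage oil, the glyoxylate cycle, photosynthesis, stress, other tissues and further themes, were not run. The levels of the targeted gene in the mutant are therefore not analysed here.

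Chromosome positions were examined only after the gene results had been seen. Expressed genes (mean of at least 2 CPM, 36440 genes on the 19 chromosomes) were grouped in 1 Mb windows with at least 20 such genes, which gave 694 windows. The median log2 fold change of each window was set against 10000 random draws of as many expressed genes, and the p-values were adjusted by Benjamini-Hochberg. Runs of at least 3 adjacent called windows, in order of the windows tested, were taken as segments. On shuffled fold changes the method recovered a planted segment. It found 0 segments in 100 shuffled genomes, but these were searched with fewer random draws per window. The smallest possible p-value was then larger and calls were harder to reach, so 0 was likely in advance. Values per library are medians of the log2 ratio of CPM, with 0.5 added, to the mean of the WT libraries (for a WT library, of the other WT libraries), minus the same median over all expressed genes. Chromosomes were compared with Fisher's exact test on genes higher against genes lower, which treats genes as independent. A search for windows whose level varied within the WT used an offset of 0.1 CPM, at least 15 tested genes and a range above 0.7 on the log2 scale.

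Alternatives fixed at the outset were DESeq2 size factors, library size alone, no filter on low counts, at least 1 CPM in at least 3 libraries, the replicate number as a block, each library left out, DESeq2 1.42.0, limma voom (limma 3.58.1), edgeR with robust dispersion, a removed trend with gene length (lowess span 0.3) and omission of the 100 genes with the most counts. Omission of the segments and of the variable windows, other segment settings and all alternatives for the subgenome shares were chosen after seeing the data. Exact permutation tests were two-sided. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for all steps outside R.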

Results

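Transcript levels were measured by RNA sequencing in cotyledons of Brassica napus seedlings of the wild type (WT) and of a bnsdp1 mutant, with 3 libraries each. SDP1 (SUGAR-DEPENDENT1) is a lipase that starts the breakdown of stored oil in germinating seeds, and the design asks how a disturbed lipid metabolism in the cotyledon affects expression at the seedling stage. The WT libraries held 56801337, 65550668 and 51404121 counts in genes, and the mutant libraries 48288744, 54965583 and 54358576. Libraries of the same genotype correlated at 0.973 to 0.986 across genes (Pearson's r of log2 CPM), and libraries of different genotype at 0.851 to 0.892; genes are not independent replicates. The first principal component held 80.3% of the variance and separated the genotypes. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was at least 7.63 within a genotype.

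The bnsdp1 mutant cotyledons differed from WT in 29152 of 56385 tested genes (51.7%), of which 14365 were higher and 14787 lower in the mutant (edgeR, FDR under 0.05). The median change was 0.76 on the log2 scale among the higher genes and -0.99 among the lower ones. At least 2-fold changes were found for 12547 genes, with 5207 higher and 7340 lower. At least 4-fold changes were found for 1859 higher and 2796 lower genes, and at least 16-fold changes for 488 higher and 558 lower genes. The 3 mutant values lay wholly above or wholly below the 3 WT values in 61.1% of tested genes, against 10% by chance. The common biological coefficient of variation was 0.145. The remaining 27233 genes did not pass the threshold.

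**Figure D1:**
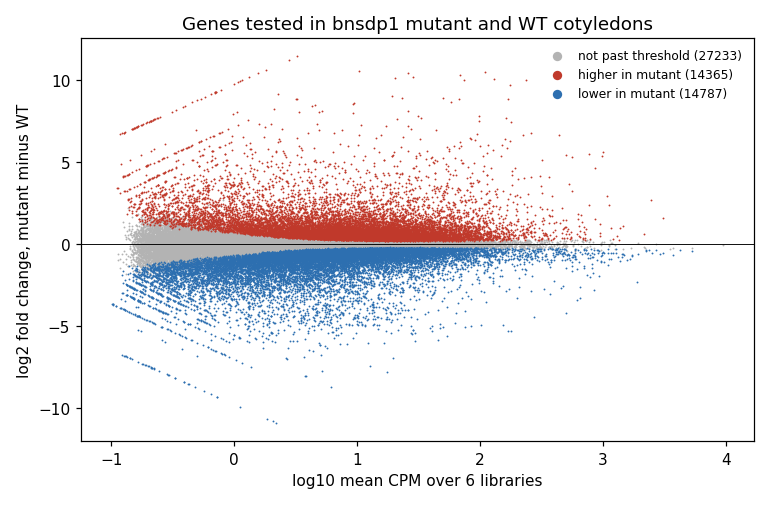
Log2 fold change of each tested gene, mutant minus WT (vertical axis), against the log10 of its mean CPM over the 6 libraries (horizontal axis). The 14365 genes called higher are red, the 14787 called lower are blue and the 27233 others are grey; low genes need larger changes to pass.

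The balance of rises and falls differed with the level of the gene. Of the 14097 genes with the lowest mean level (up to 1.13 CPM), 31.5% changed, and 35.2% of those were higher in the mutant. Of the 14096 genes with the highest level (from 12.9 CPM), 67.7% changed, and 58.8% of those were higher. At least 2-fold falls were found for 18.8% of the lowest and 7.02% of the highest genes. For at least 2-fold rises the shares were 10.1% and 10.5%. Mutant libraries also had fewer genes with any read: after thinning each library to 48288744 counts, 66415 ± 413 genes had a read in WT and 65605 ± 234 in the mutant (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

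Among genes with a mean of at least 5 CPM, the largest rises reached from nearly no reads in WT to clear expression in the mutant. BnaA01G0013200ZS (chromosome A01, 820221 to 821632, plus strand) rose from 0.0102 ± 0.0177 to 20.7 ± 3.16 CPM (SD, n = 3), a fitted log2 fold change of 10.57 (SE 0.324, edgeR adjusted p = 9.67e-09). Its WT value rests on 2 reads, all in WT replicate 2, and the ratio of mutant to WT reads, pooled over libraries and divided by pooled library size, was 1811 with a 95% counting interval of 501 to 14957. BnaA04G0017900ZS (chromosome A04, 1149895 to 1156902, minus strand) rose from 0.156 ± 0.136 to 218 ± 51.5 CPM (log2 fold change 10.49, SE 0.407, edgeR adjusted p = 3.95e-08). It had 14, 0 and 12 reads in the WT libraries, and its log2 fold change was 9.82 without WT replicate 2. Without that library BnaA01G0013200ZS had no WT read, and its fitted value of 13.10 then depends on the prior count and is no bound.

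The largest falls went the other way, from clear expression in WT to a few reads. BnaC09G0050100ZS (chromosome C09, 3223525 to 3224822, plus strand) fell from 12.1 ± 5.65 to 0.0249 ± 0.0216 CPM (log2 fold change -8.75, SE 0.576, edgeR adjusted p = 1.16e-06). It had 2064 reads over the WT libraries and 4 over the mutant libraries. BnaA09G0649200ZS (chromosome A09, 62108802 to 62112918, minus strand) fell from 34.9 ± 12.2 to 0.155 ± 0.0363 CPM (log2 fold change -7.80, SE 0.341, edgeR adjusted p = 7.99e-08), with 6008 and 24 reads. The ratio of WT to mutant reads, pooled and divided by pooled library size, was 455 for BnaC09G0050100ZS (95% counting interval 178 to 1673) and 221 for BnaA09G0649200ZS (148 to 345). The files do not pair these identifiers with names, and the genome build of the coordinates is not given in the sources used here.

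Some genes were read in 1 genotype alone. In the mutant, 59 genes had at least 10 reads in each library and 0 reads in all WT libraries, 26 of them on A chromosomes and 32 on C chromosomes. Conversely, 43 genes had at least 10 reads in each WT library and 0 in all mutant libraries, 22 on A and 21 on C chromosomes. Their median level was low, at 22.7 reads per mutant library for the former and 24.7 reads per WT library for the latter, and a count of 0 over a genotype allows up to 3 reads. None of these genes lay in the chromosome segments described next.

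Expression of 4 chromosome segments shifted as a block in the mutant. On chromosome A07, the 427 expressed genes between 27 and 32 Mb had a median log2 fold change of -0.57 relative to all expressed genes, with 202 genes called lower and 35 higher. On chromosome C06, the 363 genes between 46 and 51 Mb had a relative median of 0.42, with 208 called higher and 57 lower. At the start of chromosome A01, the relative median was -0.36 for both the 303 genes between 0 and 3 Mb (151 lower, 53 higher) and the 379 genes between 4 and 9 Mb (189 lower, 59 higher). BnaA01G0013200ZS lies in the former of these and rose against it. With 2 Mb windows, a setting chosen after seeing the data, the search gave 1 lower segment on A01, from 0 to 10 Mb. A search of 100 genomes with shuffled fold changes, in which neighbouring genes share nothing, found 0 segments. It used fewer random draws per window, which made calls harder, so the 0 does not measure how often chance gives a segment.

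Shifts of the A07 and C06 segments differed between mutant libraries, while those of A01 were alike. On A07 the library medians relative to WT were -0.46, -0.24 and -1.07 in mutant replicates 1, 2 and 3, with a mean of -0.59 ± 0.43 (SD, n = 3). On C06 they were 0.33, 0.24 and 0.62, with a mean of 0.40 ± 0.20. In the A01 segment from 0 to 3 Mb they were -0.37, -0.31 and -0.37, and in that from 4 to 9 Mb -0.37, -0.30 and -0.36. All WT library medians of the 4 segments lay between -0.02 and 0.03. Each segment gave an exact two-sided permutation p of 0.1 over the libraries, the smallest possible for 3 against 3, which follows in part from choosing the segments in the same libraries. Without mutant replicate 3, the relative median was -0.36 on A07 and 0.28 on C06.

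**Figure D2:**
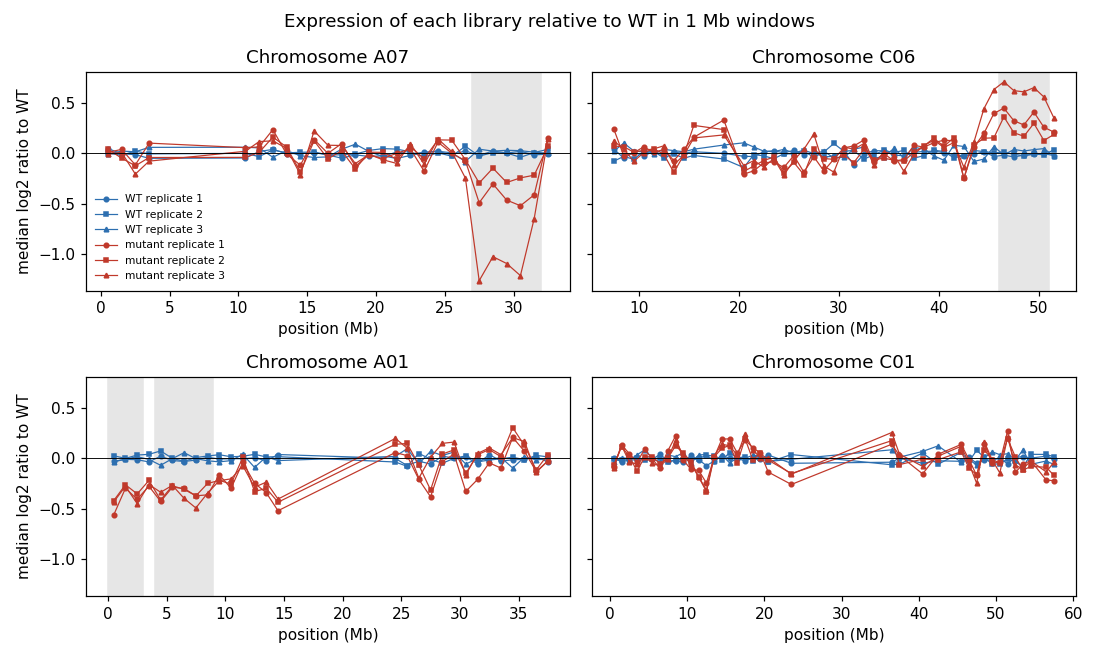
Median log2 ratio of expressed genes to WT in 1 Mb windows (vertical axis) along 4 chromosomes (position in Mb, horizontal axis), with a line for each WT library (blue) and mutant library (red); grey bands mark the segments. Mutant replicate 3 reaches a median of -1.07 over the A07 band and 0.62 over the C06 band, and no part of C01 is marked.

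Whole chromosomes were also compared, on calls from the same fit that gave the segments, so this is no separate support for them. Among called genes, the share higher in the mutant was 34.4% on A01, 40.5% on A07 and 58.4% on C06, the most extreme of the 19 chromosomes (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.45e-29, 4.76e-10 and 1.87e-11). On A06 and C05 the shares were 52.8% and 52.4% (adjusted p = 0.0264 for each). The segments were chosen for their direction. With them left out, the share was 49.0% on A07 (Fisher's exact adjusted p = 0.736) and 53.4% on C06 (adjusted p = 0.141). A01 stayed low at 42.2% (adjusted p = 0.000112), and A06 and C05 had an adjusted p of 0.141. The A01 fall was not confined to the segments. In the gap between them the window median log2 fold change was -0.20. This value and the next window medians are not relative to all expressed genes, whose median was 0.053. From 9 to 15 Mb the window medians were -0.19, -0.23, 0.04, -0.29, -0.35 and -0.46 in order, the last called lower (random draws, adjusted p = 0.00867). From 15 Mb to the end of A01 the median shift, which unlike the window medians is a relative value, was 0.017. Called neighbours went in the same direction in 56.9% of pairs, against at most 51.2% after shuffling, so the Fisher tests over genes overstate the evidence.

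**Figure D3:**
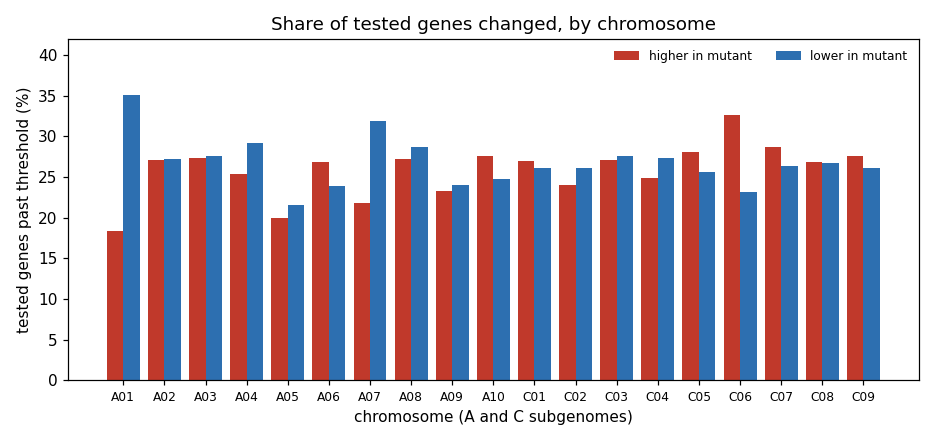
Percentage of tested genes called higher (red) and lower (blue) in the mutant (vertical axis) on each A and C chromosome (horizontal axis). On A01 18.4% of genes were higher and 35.1% lower, on A07 21.8% and 31.9%, and on C06 32.6% and 23.2%.

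A slightly smaller share of counts came from the A subgenome in the mutant libraries than in the WT libraries. Genes on A chromosomes held 48.2% ± 0.213 of counts in WT and 47.5% ± 0.243 in the mutant (SD, n = 3), a difference of -0.744 percentage points (exact two-sided permutation p = 0.1, the smallest possible). C chromosomes held 51.7% ± 0.228 and 52.4% ± 0.238. Without the genes of the 4 segments the A shares were 46.9% ± 0.220 and 46.7% ± 0.0811, a difference of -0.184 points (exact permutation p = 0.3, n = 3). Among called genes, 47.3% on A and 51.1% on C chromosomes were higher in the mutant (Fisher's exact p = 1.95e-10), and 49.2% and 50.5% outside the segments (p = 0.0288).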

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

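The count of changed genes stayed between 25676 and 29936 under 18 settings, and that of at least 2-fold changes between 9372 and 13414, all within 1.5 times the values reported; leaving out single libraries gave 25676 to 28634 and 12050 to 12641. DESeq2 called 28388 genes and limma voom 29415; the share of called genes that were higher, 49.3% as reported, was 45.7% with library size alone and 50.8% with the gene length trend removed, and without WT replicate 3 higher genes also outnumbered lower ones (14609 and 14025). The 4 named genes kept their direction and call in every setting run, with edgeR, DESeq2 or limma adjusted p of at most 0.00146. Same-numbered libraries deviated together at r = 0.21, -0.06 and 0.07, and not every library correlated best with its own number. Differently numbered pairs ranged from -0.22 to 0.18. Deviations of the 3 libraries of a genotype offset each other, so these values neither show nor exclude a pairing. The replicate block gave 28376 changed genes and 12368 at least 2-fold, and ended no call of a named gene. With settings chosen after seeing the data, 3 to 4 segments were found, and the A subgenome difference was -0.1843 points without the segments' genes, which that setting removes, against -0.98 without the 100 genes with the most counts. Leaving out single libraries moved the A07 median from -0.77 (without mutant replicate 2) to -0.36 (without mutant replicate 3), and the C06 median from 0.28 to 0.51. Intended settings for the SDP1 copies and the 32 gene lists, with copies summed, camera and fry among them, were not run. How many changed genes were missed at this depth is not known.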

Other observations

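All tests in this part were chosen after the results they bear on had been seen. Beyond the segments, called genes that lie next to each other went in the same direction in 56.4% of 15554 pairs, against at most 51.5% after shuffling directions (permutation p = 0.001, the smallest that 1000 shuffles can give). Within the mutant, the A07 segment held 150 of the 500 most variable genes with a mean of at least 10 CPM, although it holds 1.08% of such genes, and the C06 segment held 13. When each library was set against the others of its genotype, mutant replicate 3 stood apart on A07 from 26 to 32 Mb by -0.69 on the log2 scale, with 91.6% of 499 genes on that side, and on C06 from 44 to 52 Mb by 0.31, with 92.9% of 510 genes. Mutant replicate 2 stood apart the other way on the same stretches, by 0.47 on A07 (89.6% of genes) and -0.23 on C06 (88.8%). Mutant replicate 1 differed by 0.19 on A07 and by -0.16 on A01 from 28 to 34 Mb. As each library was set against the mean of the others, deviations within a genotype offset each other. Those of mutant replicates 1 and 2 on A07, and of replicate 2 on C06, thus follow in part from replicate 3. Runs of windows found in single WT libraries were weaker, at most 0.15 in size, on A06, A02 and C02.

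Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real split, gave 29152 changed genes or 12547 at least 2-fold; the highest count in the other splits was 0 for both in edgeR, with 256 to 669 genes at an unadjusted p under 0.05 against 32225 in the real split. The 10 splits are too few for a share under 0.05. Every other split mixed the genotypes, so their difference widened the spread within its groups and kept its calls low. The count of 0 therefore does not measure how many calls chance would give.

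The A07 and C06 segments moved in opposite directions by amounts that varied together over the mutant libraries, with A07 at 0.729, 0.848 and 0.478 of the WT level in replicates 1, 2 and 3, and C06 at log2 shifts of 0.33, 0.24 and 0.62. Each window of both segments had a Benjamini-Hochberg adjusted p under 0.05 against random draws of expressed genes, which is the rule that chose the segments. The draws also do not allow for neighbours that change together, as called genes outside the segments did. Within these limits, as the adjustment covered all 694 windows, such runs argue against separately regulated genes that adjoin by chance. The 0 of 100 shuffled genomes with a segment cannot decide it, as they were searched with fewer draws. A fixed sequence difference that moves reads between copies is argued against, as the mutant libraries ranged 25.7 times as widely as the WT libraries on A07. That value rests largely on mutant replicate 3. On C06 the mutant and WT ranges were 0.381 and 0.0505. A candidate explanation is an exchange in which copies of the A07 segment are replaced by their C06 counterparts in a share of seedlings that differs between libraries. The linear ratios of both segments to WT would then sum to 2, and the sum farthest from that in a mutant library was 2.03. Other opposite shifts of like size also sum to near 2, and WT replicate 3, with hardly any shift, gave 2.04. The sums therefore do not single out an exchange. The exchange is a hypothesis from RNA alone: no DNA copy number was analysed here, and the shared ancestry of the segments was not tested by sequence. Joint regulation of neighbouring genes was not tested and stays open, as does whether such a difference came with the bnsdp1 line or from the WT stock it was compared with, or follows from the mutation.

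The A01 segments fell by similar amounts in all 3 mutant libraries. Whether separately regulated genes adjoin there by chance cannot be decided, as above, by the 0 of 100 shuffled genomes with a segment. Windows of the A01 segments passed the same adjusted threshold against random draws, with the same limits as on A07 and C06. The first 15 Mb of C01 had a median shift of 0.0032, which would argue against an exchange that adds C01 copies only if that part were the counterpart of the A01 segments; this was not tested by sequence, so such an exchange stays open. The 10th percentile shifted by -0.59 against -0.37 for the median, a difference of -0.22 (95% bootstrap interval over genes -0.36 to -0.06). For the 25th percentile the interval was -0.157 to -0.003, but those of the 75th (-0.03 to 0.09) and 90th (-0.10 to 0.12) included 0. These intervals treat neighbouring genes as independent and may be too narrow. Whether a lower copy number that lowers all genes alike is the whole cause therefore cannot be decided. The upper quartile shifted by -0.34, 0.93 times as far as the median, and the 90th percentile by -0.39. A lower copy number would give this, but so would any other cause that shifts most genes of the region. Whether a lower copy number is part of the cause therefore stays open. Joint regulation of neighbouring genes, an effect of the mutation and a difference between the plant stocks were not tested and stay open.

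In 35 windows of 1 Mb, on A01, A05, A06, A09, C08 and unplaced sequences, the WT libraries differed from each other by at least 0.84 on the log2 scale, while no other of 799 windows exceeded 0.56. Summed levels there were 3168, 2648 and 1520 CPM in WT replicates 1, 2 and 3 and 3648, 2308 and 2644 CPM in the mutant replicates, so that the genotypes overlapped (exact permutation p = 0.6, n = 3). In the mutant libraries, which had no part in choosing the windows, 87.3% of their genes were highest in replicate 1. A single common source of RNA whose amount differs between libraries may thus underlie them. Over 825 genes of the windows, however, log2 ratios of WT replicate 3 to WT replicate 1 had an SD of 0.576. Counting alone would give 0.290, so counting error around 1 common factor does not account for all of this spread. Genomic DNA in the libraries is argued against, since it would vary alike in genes elsewhere with as few reads per kb, but 35.1% of those 13541 genes were highest in mutant replicate 1. What that source is, and whether it follows handling or tissue, cannot be read from the labels, and no biological explanation was tested.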
